A study of Mus musculus with 36 samples.

How the data were processed

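Heart RNA from 36 female C57BL/6 mice was measured on 36 arrays of 1 Agilent design, 1 mouse per array. The sample RNA carried Cy5 and a purchased Universal Mouse Reference RNA carried Cy3 on every array, per the labels, so no dye swap exists and a dye effect is shared by all groups. Treatment and day were taken from the labels, and the replicates were individual mice according to the series design text. RNA isolation, amplification and labelling were done by the authors, as named in the labels' protocols.

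The deposited scanner files gave the intensity of each spot as the median pixel brightness in Cy5 and Cy3, with its local background, not normalized. Per the file headers, Feature Extraction 10.7.3.1 made them and also computed a log10 ratio of red over green after its own background subtraction and dye normalization. Per the file headers, the other values were marks for each spot, namely signal well above background, saturation, uneven spots and control spots. The deposited value table held a log2 ratio of Cy5 over Cy3 per spot. How the authors made it was not given in the sources used here. Its values matched a loess-normalized log2 ratio of the unsubtracted medians of the same array, with a correlation across probes between 0.989 and 0.995 and a slope between 0.977 and 0.990. No columns without a sample were present, and its empty entries were the 3671 control spots.

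The scanner files were analysed, and the value table served as an alternative. Of 62976 spots, 3671 were controls, and the rest carried 55681 distinct probes. Median signals were background corrected with limma's normexp method at an offset of 50, turned into log2 Cy5 over Cy3 and normalized by loess within each array. Control spots and outlier spots had a weight of 0 in the loess fit. Values of outlier spots, 0.0851% of all probe values, were left out, and repeated spots of a probe were averaged. A probe was tested if its Cy5 signal was well above background on at least 6 of 36 arrays and at least 30 arrays had a value. This left 34193 probes, of which 13682 were well above background on all arrays. No spot was saturated, and 0 pairs of arrays held identical values.

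Probes were matched to gene symbols by the RefSeq transcript given for each probe and the RefSeq annotation of mouse assembly GRCm38. A symbol was found for 26413 probes of 20018 genes, and 29268 probes stayed unnamed. Among tested probes, 19158 carried a symbol, for 14951 genes. Probe positions were not remapped.

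All 36 arrays entered 1 fit with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8, for reading), with 6 group means, 30 residual degrees of freedom and moderated statistics. Carbon black was compared with control on each day and as the mean of the 3 daily differences, the effect was compared between days with an F test, and the control mice of days 3 and 28 were compared with those of day 1. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested in that comparison. Standard errors are those of the moderated fit. The slide of each array was not part of the planned model, and the same fit with slide as a fixed term is given beside it.

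Genes were named by a rule. It gave the 10 largest rises and falls among called probes and, where fewer than 10 were called, the 5 genes with the smallest p in each direction as values. It added the members of each list that passed adjusted over the list alone, otherwise up to 4 members with the smallest p, and a fixed set of 18 genes. A list gene was represented by its probe with the highest mean intensity. Below, members are named for lists that were called. Some genes that the rule would name are not given here.

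The fixed lists numbered 34, made of 17 gene lists and 17 lists of cell type or tissue markers. They were tested with camera in limma at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over 136 pairs of list and carbon black comparison. Lists in the other comparisons were adjusted apart from these. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. A list score per mouse was the mean over members of the log ratio minus that gene's mean over all arrays. Scores of the 18 carbon black and 18 control mice were compared by a two-sided permutation test with 100000 permutations within days, adjusted over 34 lists.

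Alternatives covered background correction, normalization, the filter on dim probes, slide as a fixed or random term, the arrays in the fit, the variance model, the source of the values, the threshold and leaving out each array. Those with slides 4 and 5 left out, scaling of ratios between arrays, estimated correlation together with slide, and list tests with each array left out were chosen after the data were seen. The fit was tested on simulated data in 5 draws. Mice were exchanged between groups within each day. A change of 1.5, 2 or 3 fold, up or down, was then added to the normalized log2 ratios of 200 of 34193 probes. Array data carry no read depth, and the number of arrays limits the precision. Other tissues of these mice and other doses were not analysed here.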

Results

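Hearts were sampled 1, 3 or 28 days after female C57BL/6 mice received vehicle or 162 µg of Printex 90 into the trachea. Printex 90 is an industrial carbon black of nanometre-sized particles, and the cardiac RNA came from a random section with both ventricles. Each of the 6 groups held 6 mice. Expression was measured as the log2 ratio of the heart RNA to a common reference RNA, on 1 array per mouse.

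The share of probes with Cy5 signal well above background was 47.4% ± 12.0 (SD, n = 6) in control and 48.3% ± 12.7 in carbon black hearts on day 1. It was 46.7% ± 10.6 and 51.1% ± 16.0 on day 3, and 49.8% ± 11.3 and 47.2% ± 13.1 on day 28. The spread came from the slides. The 21 arrays of slides 1 to 3 ranged from 48.5% to 68.3% and the 15 arrays of slides 4 and 5 from 29.0% to 40.1%, while Cy3 ranged from 67.7% to 86.9% and from 67.7% to 79.3%. Slide accounted for 96.7% of the first principal component, which held 48.9% of the variance, and treatment for 0.0260%. Each slide carried carbon black and control mice, and slide 1 carried no control mouse of day 3.

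**Figure D1:**
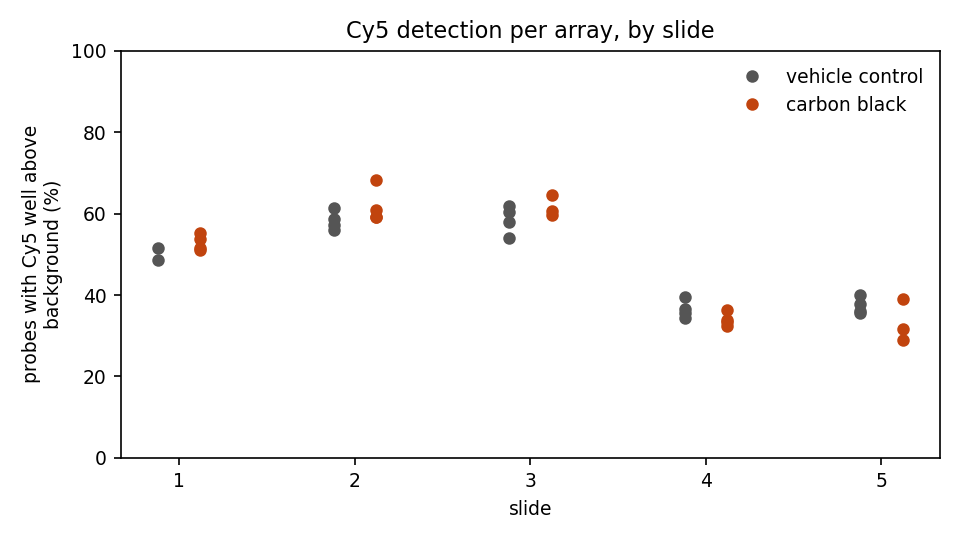
Percentage of probes with Cy5 signal well above background (vertical axis) for each of the 36 arrays (points), by slide (horizontal axis), with vehicle control in grey and carbon black in orange. Arrays of slides 4 and 5 lie between 29.0% and 40.1%, below all arrays of slides 1 to 3, and both treatments occur on each slide.

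Whether carbon black went with a cardiac difference shared by the 3 days was asked with 18 against 18 mice. Glucocorticoid targets, genes that the glucocorticoid receptor induces, were lower in carbon black hearts, with a median log2 difference of -0.22, 13 of 15 measured members lower and a camera adjusted p of 7.04e-11. Ddit4, an inhibitor of mTORC1 signalling, differed by -0.58 ± 0.16 (SE), the kinase gene Sgk1 by -0.46 ± 0.15 and the clock repressor Per1 by -0.44 ± 0.14. These 3 were lower adjusted over the list alone, with adjusted p of 0.0110 for Ddit4 and 0.0207 for Sgk1 and Per1. Over all probes 0 members passed. The other 12 passed neither way in the fit without slide, among them Tsc22d3, which encodes the anti-inflammatory protein GILZ, at -0.26 ± 0.099. With slide in the model 8 of the 15 were lower adjusted over the list alone, Tsc22d3 among them (-0.30, adjusted p 0.00153). The 2 members that went the other way were Angptl4, a lipoprotein lipase inhibitor, at 0.45 ± 0.27 and Pdk4 at 0.04.

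The glucocorticoid score was -0.099 ± 0.21 (SD, n = 18) in carbon black and 0.099 ± 0.20 in control mice, and 15 of 18 carbon black mice lay below the control mean of their day. The two-sided permutation p of this difference of -0.20 was 0.00812, or 0.276 adjusted over the 34 lists. Within slides 1 to 5 the score differed by -0.091, -0.11, -0.18, -0.40 and -0.32. Differences within slides, here and below, took no account of day. With slide in the model the median was -0.23 and the adjusted p 1.36e-09. The call held with an estimated correlation at an adjusted p of 0.0117, but not with slide and an estimated correlation together (0.231) or by fry (0.223). It was the 1 call of 25 that held with an estimated correlation alone. On slides 1 to 3 alone, the glucocorticoid calls held for the mean of the days (adjusted p 0.0175) and day 28 (0.00860) and were lost on day 1 (0.0641) and day 3 (0.742).

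**Figure D2:**
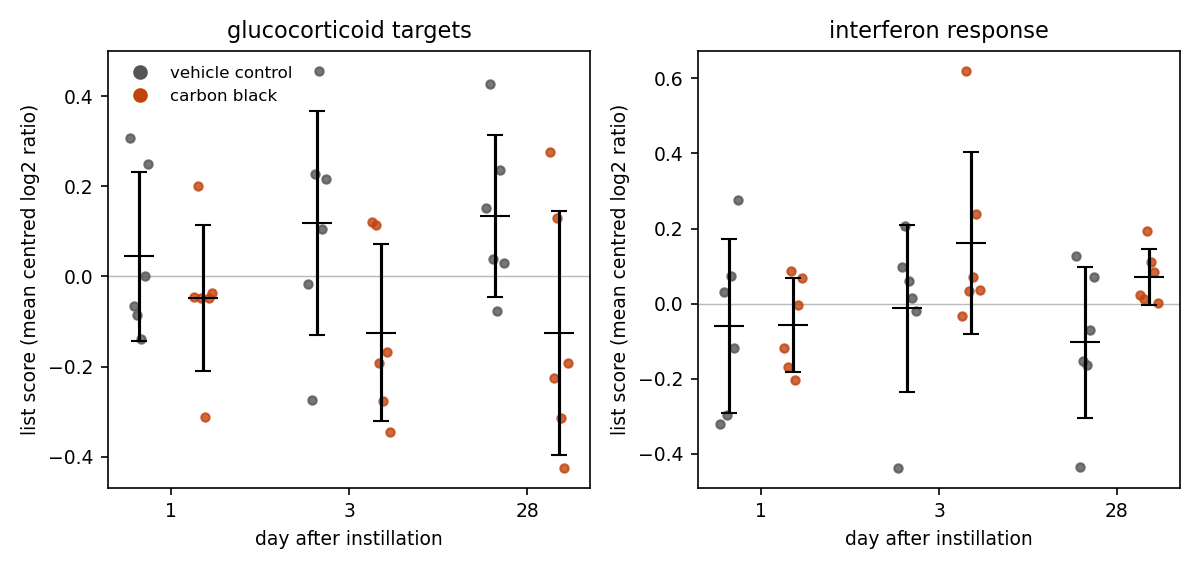
List score per mouse (vertical axis, mean centred log2 ratio) for glucocorticoid targets (left) and interferon response (right) by day after instillation, with points for mice and bars for the mean ± SD of 6 mice. Glucocorticoid scores of 5 of 6 carbon black mice lie below the control mean on each day, and interferon scores of 3, 5 and 6 of 6 lie above it on days 1, 3 and 28.

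Interferon response genes were higher in carbon black hearts for the mean of the days, with a median of 0.11, 21 of 23 members higher and an adjusted p of 2.45e-07. With slide in the model the median was 0.13 and the adjusted p 3.53e-07, and with an estimated correlation the adjusted p was 0.479. Of the members, 0 rose or fell over all probes or adjusted over the list alone. Those with the smallest p were Ifi27l2a at 0.34 ± 0.15, the ubiquitin-like modifier Isg15 at 0.19 ± 0.092, the antiviral enzyme Rsad2 at 0.20 ± 0.12 and Ifit1 at 0.19 ± 0.11. The score differed by 0.12, with 14 of 18 carbon black mice above the control mean of their day, a permutation p of 0.0766 and an adjusted p of 0.935. Within slides 1 to 5 it differed by 0.022, 0.37, 0.12, 0.087 and -0.017.

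Genes of the circadian clock were lower, with a median of -0.063, 12 of 16 members lower and an adjusted p of 0.00206. With slide the median was -0.097 and the adjusted p 0.00228, and with an estimated correlation the adjusted p was 0.357. The score was lower in 12 of 18 carbon black mice and differed within slides by 0.020, -0.15, -0.097, -0.22 and -0.093. Beside Per1, the repressor genes Ciart (-0.42 ± 0.17) and Per2 (-0.21 ± 0.085) and the output gene Tef (-0.14 ± 0.089) had the smallest p, and 0 of the 16 passed adjusted over the list alone, against 5 with slide. Erythroid and blood markers were higher, with a median of 0.19, 6 of 6 members higher and an adjusted p of 0.000376, against 0.617 with an estimated correlation and 0.00539 with slide (median 0.13). Their score was higher in 11 of 18 carbon black mice and differed within slides by 0.20, 0.33, 0.53, -0.29 and 0.18. The permutation p of this score was 0.156, or 0.935 adjusted. The haem synthesis gene Alas2 differed by 0.35 ± 0.32, the alpha globin gene Hba-a2 by 0.18 ± 0.16 and the anion exchanger gene Slc4a1 by 0.15 ± 0.11, and 0 of 6 passed adjusted over the list alone, against 1 with slide.

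**Figure D3:**
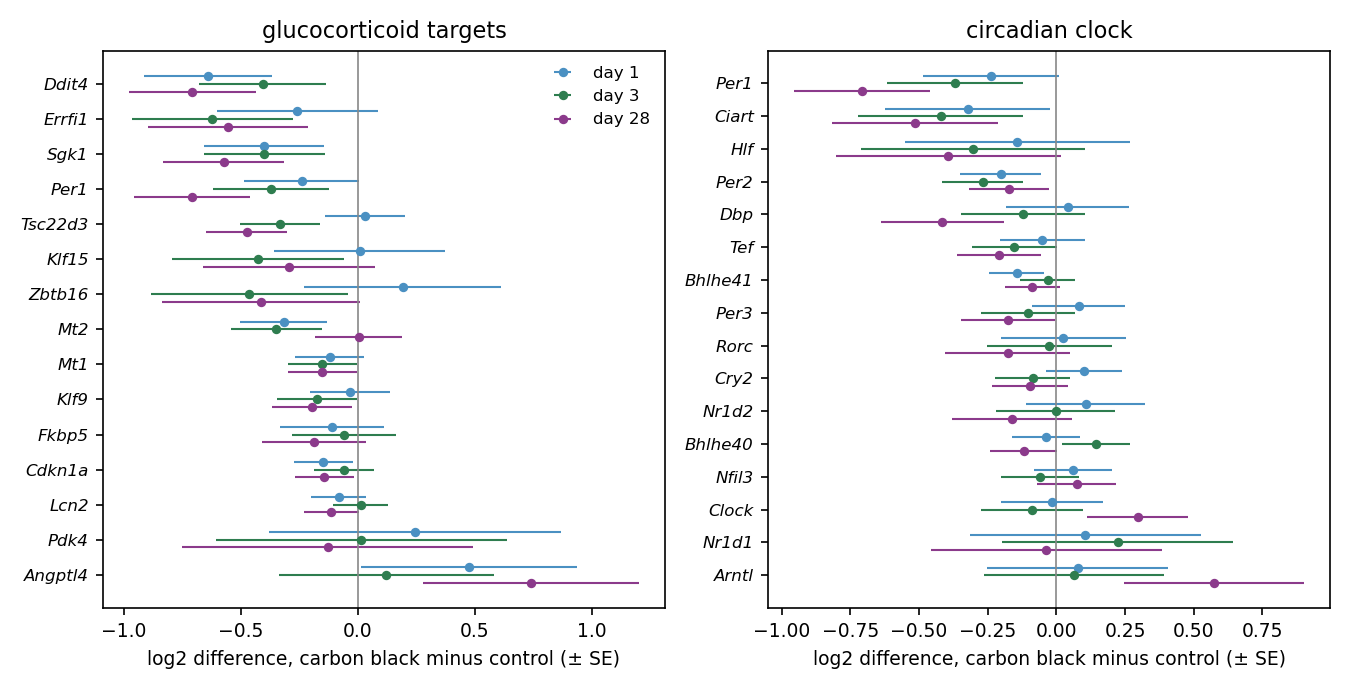
Log2 difference between carbon black and control hearts (horizontal axis, ± SE, 6 mice per group) on days 1, 3 and 28 for each measured member of the glucocorticoid target list (left) and the circadian clock list (right). Ddit4, Sgk1 and Per1 lie below 0 on all 3 days.

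Another 5 lists were called for the mean of the days, and all 5 calls were lost with an estimated correlation. In the permutation test of their scores, each had an adjusted p of 0.935, with unadjusted p from 0.274 to 0.514. Immediate early genes were lower (median -0.088, 16 of 21 members, adjusted p 0.00903, estimated correlation 0.918, slide 0.0701). Of these the transcription factor gene Klf4 was lower adjusted over the list alone (-0.41 ± 0.11, adjusted p 0.0123), and the score was lower in 12 of 18 mice. Liver markers were lower (median -0.24, 7 of 7 members, 13 of 18 mice, adjusted p 0.0396, estimated correlation 0.918), with a slide-adjusted median of -0.33 and p of 0.0121. Serpina1a (-0.56 ± 0.50), Alb (-0.59 ± 0.55), Ahsg (-0.36 ± 0.40) and Apoc3 (-0.24 ± 0.31) had the smallest p. Fatty acid oxidation and PPAR targets were higher (median 0.048, 20 of 25 members, 11 of 18 mice, adjusted p 0.0168, estimated correlation 0.918, slide 0.402). Malonyl-CoA decarboxylase Mlycd was at 0.14 ± 0.057, the lipase gene Lpl at 0.11 ± 0.084 and the fatty acid carrier gene Fabp3 at 0.19 ± 0.15. Adipocyte markers were higher (median 0.12, 6 of 7 members, 9 of 18 mice, adjusted p 0.0362, estimated correlation 0.904, slide 0.265), with Fabp4 at 0.12 ± 0.078, Adipoq at 0.41 ± 0.30, Retn at 0.36 ± 0.26 and Cfd at 0.68 ± 0.69. Skeletal muscle markers were lower (median -0.079, 5 of 5 members, 10 of 18 mice, adjusted p 0.0478, estimated correlation 0.904, slide 0.431), with the calcium-binding protein gene Pvalb at -0.19 ± 0.091.

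Among single genes, Klf2, a transcription factor gene that responds to blood flow in endothelium, had the smallest p of any named gene for the mean of the days. It differed by -0.72 ± 0.15, was lower in 17 of 18 carbon black mice, and had an unadjusted p of 3.17e-05 and an adjusted p of 0.541. With slide in the model it differed by -0.72 with an adjusted p of 0.395. Without control day 3 replicate 15 it differed by -0.79 and passed, with an adjusted p of 0.0333. The alpha-arrestin gene Arrdc2 was at -0.61 ± 0.14 (16 of 18 mice lower), the immediate early gene Csrnp1 at -0.40 ± 0.094 (17 of 18), the salt-inducible kinase gene Sik1 at -0.53 ± 0.14 (15 of 18) and the differentiation inhibitor gene Id1 at -0.29 ± 0.075 (15 of 18). On the higher side were the splicing kinase gene Clk1 at 0.24 ± 0.066 (18 of 18 mice higher), the ubiquitin ligase gene Mkrn1 at 0.21 ± 0.058 (15 of 18) and the lysophosphatidic acid receptor gene Lpar6 at 0.24 ± 0.072 (15 of 18). Hnrnpa3, an RNA-binding protein gene with 1 of 7 probes of the opposite sign, was at 0.20 ± 0.061 (16 of 18), and the NEDD8 protease gene Senp8 at 0.19 ± 0.058 (16 of 18). These counts compare each carbon black mouse with the control mean of its day. Since the genes were picked by p in the same data, the counts add no support of their own. Limma called 0 of 34193 probes, and 604 had an unadjusted p under 0.05, where evenly spread p-values would give 1709.65. With slide 0 were called and 2202 had an unadjusted p under 0.05. In 100 splits that exchanged mice within days, 79, the real one included, gave at least 604 such probes (median of the others 952). With slide, 21 of 100 gave at least the 2212 that the real grouping had in that run (median of the others 1570). Neither count thus stood apart from regrouped mice. The median SE was 0.081, or 0.056 with slide.

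No inflammatory or cardiac stress gene of the fixed set passed for the mean of the days. The lung acute phase gene Saa3 differed by -0.02 ± 0.22, Lcn2 by -0.06 ± 0.068, the chemokine genes Ccl2 by -0.04 ± 0.094 and Cxcl1 by 0.08 ± 0.21, and the natriuretic peptide genes Nppa by -0.06 ± 0.16 and Nppb by -0.04 ± 0.25. The haem oxygenase gene Hmox1 differed by 0.000073 ± 0.081, the metallothionein gene Mt2 by -0.22 ± 0.11, the adhesion molecule genes Icam1 by 0.01 ± 0.065 and Vcam1 by 0.09 ± 0.085, and Nos3 by 0.07 ± 0.089. The metabolic kinase gene Pdk4 differed by 0.04 ± 0.36, the glucocorticoid target Fkbp5 by -0.12 ± 0.13, and the clock genes Dbp by -0.17 ± 0.13 and Arntl by 0.24 ± 0.19. With slide in the model, Saa3 differed by 0.11 ± 0.080, Nppa by -0.16 ± 0.089, Cxcl1 by 0.15 ± 0.073 (unadjusted p 0.0448, adjusted p 0.766), Mt2 by -0.23 ± 0.089 (0.0151 and 0.735) and Arntl by 0.29 ± 0.099 (0.00647 and 0.681). Saa3, Ccl2, Icam1 and Pdk4 took the other sign with slide. Il6 was above background on 0 arrays and Cyp1a1, a target of the aryl hydrocarbon receptor, on at most 1, so neither was tested.

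The other 12 gene lists were not called for the mean of the days, with adjusted p from 0.0620 to 0.979. Their medians were -0.056 for acute phase, 0.038 for chemokines and cytokines, 0.017 for endothelial activation and clotting, -0.0018 for oxidative stress and Nrf2 targets, 0.022 for aryl hydrocarbon receptor targets and -0.0011 for cardiac stress genes. They were 0.034 for extracellular matrix and fibrosis, -0.018 for sterol synthesis, 0.027 for oxidative phosphorylation, 0.0097 for heat shock and unfolded protein response, -0.00012 for cell cycle and 0.068 for calcium handling and sarcomere. The other 13 cell type lists were not called either, with adjusted p from 0.0828 to 0.816. Their medians were 0.085 for cardiomyocyte, 0.098 for ventricle, -0.047 for atrium, 0.041 for endothelium, 0.065 for fibroblast, 0.078 for smooth muscle and pericyte and 0.042 for macrophage and monocyte. They were 0.018 for neutrophil, -0.030 for T cell, 0.053 for B cell, 0.025 for lung epithelium, 0.10 for mesothelium and 0.049 for thymus.

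On day 1, carbon black hearts had higher fatty acid oxidation and PPAR targets (median 0.13, 22 of 25 members higher, 6 of 6 mice, adjusted p 0.000762) and higher adipocyte markers (0.24, 7 of 7 members, 4 of 6 mice, adjusted p 0.00121). Erythroid and blood markers were also higher (0.24, 6 of 6 members, 4 of 6 mice, adjusted p 0.0334). Glucocorticoid targets (-0.11, 10 of 15 members lower, 5 of 6 mice, adjusted p 0.00595) and skeletal muscle markers (-0.12, 4 of 5 members, 4 of 6 mice, adjusted p 0.0396) were lower. With an estimated correlation the adjusted p-values were 0.904, 0.393, 0.918, 0.583 and 0.904 in that order, and with slide they were 0.276, 0.0597, 0.598, 0.00918 and 0.676. No member of these lists passed over all probes or adjusted over the list alone, with or without slide. The adipokine gene Adipoq was at 0.90 ± 0.52, Retn at 0.76 ± 0.45, Cfd at 1.51 ± 1.19, Cidec at 0.24 ± 0.20, Ddit4 at -0.64 ± 0.27, Mt2 at -0.32 ± 0.19, Sgk1 at -0.40 ± 0.26 and Pvalb at -0.32 ± 0.16. The adipocyte call ended without carbon black day 1 replicate 5 (adjusted p 0.771), the fatty acid call without control day 1 replicate 34 (0.123) and the glucocorticoid call without control day 1 replicate 7 or carbon black day 1 replicate 20 (highest 0.107). The erythroid and skeletal muscle calls each ended without any 1 of 7 arrays, with highest adjusted p of 0.309 and 0.410. On slides 1 to 3 alone the adipocyte call held (0.00321), the erythroid (0.225) and skeletal muscle (0.621) calls were lost and the fatty acid list turned lower (0.363).

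Among the genes with the smallest p on day 1 were, on the higher side, the oncogene family member Tcl1b4 (0.21 ± 0.075), the mitochondrial RNA-binding gene Fastkd3 (0.22 ± 0.078), Lrrc27 (0.23 ± 0.083) and the nuclear membrane gene Lemd3 (0.29 ± 0.11). On the lower side were Ezhip (-0.49 ± 0.17), Ooep (-0.29 ± 0.11), Gas2l2 (-0.30 ± 0.11), Tmem63c (-0.41 ± 0.15) and Itpripl1 (-0.29 ± 0.11). Gas2l2 and Tmem63c were above background on 0 of 6 carbon black and 2 of 6 control arrays, and Tcl1b4 (2 and 1 of 6), Lemd3 (3 and 2), Ezhip (4 and 3), Ooep (3 and 3) and Itpripl1 (1 and 3) were also dim, so these values rest on signal near background. Limma called 0 probes on day 1 with or without slide, and 257 had an unadjusted p under 0.05, or 1089 with slide.

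On day 3, interferon response genes were higher in carbon black hearts (median 0.17, 22 of 23 members, 5 of 6 mice, adjusted p 2.97e-07) and glucocorticoid targets lower (-0.33, 12 of 15 members, 5 of 6 mice, adjusted p 0.000284). Oxidative phosphorylation genes (0.080, 17 of 23 members, 4 of 6 mice, adjusted p 0.00951) and calcium handling and sarcomere genes (0.16, 16 of 18 members, 4 of 6 mice, adjusted p 0.0250) were higher. With an estimated correlation the adjusted p-values were 0.479, 0.357, 0.918 and 0.930 in that order, and with slide they were 1.35e-06, 0.000189, 0.00295 and 0.186. Isg15 was at 0.41 ± 0.16, the apoptosis factor gene Xaf1 at 0.32 ± 0.16, Tsc22d3 at -0.33 ± 0.17, the EGF receptor inhibitor gene Errfi1 at -0.62 ± 0.34, Mt2 at -0.35 ± 0.19, the cytochrome oxidase gene Cox5a at 0.15 ± 0.086 and the cardiac troponin gene Tnni3 at 0.37 ± 0.35. No member passed over all probes. Adjusted over the list alone, 0 passed without slide, and with slide Tsc22d3 was lower (-0.44, adjusted p 0.0274). The oxidative phosphorylation call ended without any 1 of 4 arrays and the calcium handling call without any 1 of 6, with the highest adjusted p of each, 0.928 and 0.445, without control day 3 replicate 40. On slides 1 to 3 alone, both of these lists turned lower (adjusted p 0.882 and 0.212). The interferon call stayed just under the threshold without control day 3 replicate 9 (camera adjusted p 0.0459). Atrium markers, not called on day 3 (median -0.17, adjusted p 0.184), had a score below the control mean in 6 of 6 carbon black mice, and cardiomyocyte (0.075) and ventricle markers (0.13) a score above it in 4 of 6.

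The smallest p of a named gene on day 3 belonged to Id1 at -0.52 ± 0.13, with an unadjusted p of 0.000357 and an adjusted p of 1.00. Next on the lower side were Olfr1170 (-0.41 ± 0.12), Klf2 (-0.87 ± 0.26), the chromatin remodelling gene Smarce1 (-0.23 ± 0.071) and Lonrf1 (-0.36 ± 0.12). On the higher side were Zfp961 (0.27 ± 0.088), the tubulin gene Tubb4b (0.55 ± 0.19), Clk1 (0.34 ± 0.12), Pnmal2 (0.44 ± 0.17) and the proton exchanger gene Slc9a8 (0.25 ± 0.093). Olfr1170 was above background on 2 of 6 arrays in each group and Pnmal2 on 5 carbon black and 1 control array. Limma called 0 probes on day 3 with or without slide, and 487 had an unadjusted p under 0.05, or 2344 with slide.

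On day 28, glucocorticoid targets were lower in carbon black hearts (median -0.20, 13 of 15 members, 5 of 6 mice, adjusted p 7.15e-07) and interferon response genes higher (0.15, 20 of 23 members, 6 of 6 mice, adjusted p 0.000142). Circadian clock genes (-0.17, 13 of 16 members, 5 of 6 mice, adjusted p 0.00493) and liver markers (-0.48, 7 of 7 members, 5 of 6 mice, adjusted p 0.00551) were lower. Erythroid and blood markers (0.22, 6 of 6 members, 3 of 6 mice, adjusted p 0.00885), mesothelium markers (0.23, 6 of 6 members, 5 of 6 mice, adjusted p 0.00885) and endothelial activation genes (0.11, 13 of 15 members, 5 of 6 mice, adjusted p 0.0362) were higher. With an estimated correlation the adjusted p-values were 0.0954, 0.904, 0.393, 0.904, 0.904, 0.904 and 0.617 in that order, and with slide they were 5.38e-07, 0.000147, 0.0347, 0.0505, 1.36e-05, 0.00919 and 0.0815. Over all probes, 0 members of these lists passed. With slide, 5 glucocorticoid targets were lower and Cxcl10 was higher (0.54, adjusted p 0.0254) adjusted over the list alone. Per1 was at -0.71 ± 0.25, Tsc22d3 at -0.47 ± 0.17, Ddit4 at -0.71 ± 0.27, Sgk1 at -0.57 ± 0.26, Rsad2 at 0.40 ± 0.20, the chemokine gene Cxcl10 at 0.79 ± 0.47, Arntl at 0.57 ± 0.33, Lrrn4 at 0.36 ± 0.26, Nos3 at 0.24 ± 0.15 and Apoa1 at -0.23 ± 0.18. The liver call ended without control day 28 replicate 12 (adjusted p 0.270) and the clock call without carbon black day 28 replicate 27 (0.132). The erythroid, endothelial and mesothelium calls ended without any 1 of 6, 6 and 4 arrays, with highest adjusted p of 0.492, 0.270 and 0.0835. On slides 1 to 3 alone the interferon (0.000396) and erythroid (1.46e-14) calls held, and the clock (0.364), liver (0.109), mesothelium (0.225) and endothelial (0.0641) calls were lost.

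Among the genes with the smallest p on day 28 were, on the higher side, Mkrn1 (0.38 ± 0.10), Lpar6 (0.44 ± 0.13), the mRNA decay factor gene Zfp36l2 (0.29 ± 0.084) and the transcription factor gene Foxp1 (0.34 ± 0.10). On the lower side were the arginyltransferase gene Ate1 (-0.33 ± 0.093), the adhesion scaffold gene Nedd9 (-0.34 ± 0.096), the non-coding RNA G6bos (-0.36 ± 0.11), the kinase gene Mapk15 (-0.37 ± 0.11) and Olfr266 (-0.31 ± 0.097). Foxp1 was above background on 3 of 6 carbon black and 1 of 6 control arrays, G6bos on 2 and 4, Mapk15 on 1 and 4, and Olfr266 on 1 and 3. Limma called 0 probes on day 28 with or without slide, and 533 had an unadjusted p under 0.05, or 1331 with slide.

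Of the 9 list calls for the mean of the days, those of glucocorticoid targets, interferon response, the circadian clock and erythroid markers stayed under the threshold with each array left out, at most at 2.01e-08, 0.000681, 0.0206 and 0.0165. The other 5 ended without any 1 of 6 arrays for immediate early genes (highest adjusted p 0.118), 12 for fatty acid oxidation (0.245), 14 for adipocyte (0.373), 18 for skeletal muscle (0.229) and 19 for liver markers (0.314). Over all 34 lists and the 4 carbon black comparisons, members passed adjusted over the list alone 5 times, or 25 times with slide. On slides 1 to 3 alone, the interferon and erythroid calls for the mean held (adjusted p 6.58e-06 and 1.98e-08), the clock call was lost (0.0839), and the 5 others were lost with adjusted p from 0.0535 to 0.882. Across scalings the medians kept their sign but not their size. With Cy5 alone, fatty acid oxidation had a median of 0.0088 with 13 of 25 members higher, erythroid markers 0.34 and liver markers -0.12. With the Feature Extraction ratio, adipocyte markers had a median of 0.45, liver markers -0.51, immediate early genes -0.16, skeletal muscle markers -0.14 and the clock -0.12. With median centring, glucocorticoid targets had a median of -0.14, the clock -0.036, immediate early genes -0.054 and skeletal muscle markers -0.050. Interferon medians lay between 0.088 and 0.13 in all scalings.

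Whether the carbon black effect differed between days was tested with an F test of the interaction. Limma called 0 probes, 202 had an unadjusted p under 0.05, and with slide in the model 0 were called and 1048 had an unadjusted p under 0.05. No gene was thereby shown to differ between days.

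The vehicle mice alone were compared over time as the background to these differences. From day 1 to day 3 the genes with the smallest p were the signal transducer gene Stat5a (0.35 ± 0.11), Wdr5b (0.35 ± 0.11), Fam32a (0.34 ± 0.11), the B cell kinase gene Blk (0.26 ± 0.087) and Fastkd3 (0.23 ± 0.078) on the higher side. On the lower side were Ly6g6c (-0.39 ± 0.13), AB124611 (-0.25 ± 0.082), Fam124b (-0.29 ± 0.099), the calcium channel gene Trpv6 (-0.23 ± 0.079) and Stum (-0.29 ± 0.10). Wdr5b, Blk, AB124611, Trpv6 and Stum were above background on at most 4 of 6 arrays in each group. Oxidative phosphorylation genes were lower (median -0.059, adjusted p 0.0466, estimated correlation 0.990), with a median of -0.087 and an adjusted p of 9.53e-05 with slide. The control mice of day 3 are also those against which this list was higher in carbon black hearts on day 3, so these differences are not independent. Limma called 0 probes, with 461 at an unadjusted p under 0.05, and 32 with slide in the model (6 higher, 26 lower), with 3762 at an unadjusted p under 0.05. With slide as a random block 0 were called (smallest adjusted p 0.363), as with a slide term on slides 1 to 3 alone (0.253), and slide 1 held no control mouse of day 3. Those 32, from which names were chosen after their values were seen, held the glycolytic gene Gapdh (-0.37), the topoisomerase gene Top1 (0.33), the mitochondrial cristae gene Immt (-0.33) and the aspartate carrier gene Slc25a12 (-0.33).

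From day 1 to day 28 the vehicle mice had higher fatty acid oxidation and PPAR targets (median 0.15, adjusted p 0.000102, estimated correlation 0.990), with a median of 0.089 and an adjusted p of 0.0174 with slide. The control mice of day 1 are also those against which this list was higher in carbon black hearts on day 1. Low values in these control mice would give both differences, which are not independent. The genes with the smallest p were Sema5b (0.49 ± 0.12), Slc6a17 (0.39 ± 0.10), Blk (0.32 ± 0.087), Fastkd3 (0.25 ± 0.078) and Zdhhc14 (0.44 ± 0.14) on the higher side. On the lower side were Slc46a3 (-0.34 ± 0.095), the fatty acid elongation gene Hacd1 (-0.37 ± 0.11), Tmem164 (-0.35 ± 0.11), Foxi2 (-0.29 ± 0.096) and the pyrimidine carrier gene Slc25a33 (-0.36 ± 0.12). Sema5b, Slc6a17, Blk, Zdhhc14 and Foxi2 were above background on at most 4 of 6 arrays in each group. Fastkd3 was higher than in control day 1 in carbon black day 1, control day 3 and control day 28. Those differences share the control mice of day 1 and are not independent. Limma called 0 probes with or without slide, and 341 had an unadjusted p under 0.05, or 1433 with slide.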

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

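Tests chosen only after the result was seen were the splits of the glucocorticoid and interferon scores and of the probe counts, the slide term as a test of the glucocorticoid score, the permutation test of the clock index (not the index as a covariate), and the immune cell lists for the interferon response.

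List scores and log2 ratios of genes were checked in each of the 6 groups of 6 mice, 240 checks in all. In 10 of these a mouse lay far from the other 5, where chance gives about 1 in 20, or 12. The checks share the same mice and are not independent, so 10 against 12 is only a rough comparison. The adipocyte score stood out in control day 1 replicate 7 (0.10), carbon black day 1 replicate 5 (2.52, against at most 0.057 in the others) and control day 3 replicate 26 (0.76). The erythroid score stood out in control day 3 replicate 40 (-1.03) and the interferon score in control day 3 replicate 9 (-0.44). The log2 ratio of Vcam1 stood out in control day 3 replicate 26 (-0.95), carbon black day 3 replicate 13 (-1.29) and carbon black day 28 replicate 6 (-0.94). Carbon black day 3 replicate 13 also stood out for Csrnp1 (1.04) and Sik1 (1.05).

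By the interaction test, the carbon black effect on 2 lists differed between days. The interferon effect was higher on day 3 than on day 1 by a median of 0.18 (adjusted p 0.000195, with slide 0.00331) and on day 28 than on day 1 by 0.18 (0.00937, with slide 0.0433). The effect on liver markers was lower on day 28 than on day 1 by a median of -0.91 (0.00937, with slide 0.307). With an estimated correlation each of these had an adjusted p of 0.999. The comparisons share the day 1 mice and are not independent.

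Glucocorticoid targets were lower in carbon black hearts, with a score difference of -0.20 for the mean of the 3 days. A constant offset between slides does not account for it, since with a slide term it was -0.23 and it was negative on 5 of 5 slides. It was larger in size on slides 4 and 5 (-0.40 and -0.32) than on slides 1 to 3 (-0.091, -0.11 and -0.18). These slide values took no account of day, and slide 1 held 4 carbon black and 2 control mice, with no control of day 3. A slide term cannot test a difference that varies with slide. On slides 1 to 3 alone the camera adjusted p for the mean of the days was 0.0175. Counting the real grouping, a score difference as large occurred in 4 of 100 splits of the mice (highest other 0.22), a count that varies with the splits drawn, where 100000 permutations gave a p of 0.00812, and with slide in 1 of 100, the real one (highest other also 0.22). The list was the strongest of 34. With estimated correlations, a list and comparison as strong occurred in the real grouping alone, 1 of 100 (-log10 p 4.07, highest other 3.88). As strong a pair occurred in 8 of 100 with slide added, 12 of 100 at the preset correlation and 23 of 100 at the preset correlation with slide. Adjusted over the 34 lists, the permutation p of the score was 0.276. The splits of the score were chosen after the result was seen. Measures that count all lists thus differed, and chance could not be excluded. An earlier or later time of day of sampling in carbon black mice may contribute, as may lower glucocorticoid signalling or handling, none of which the labels record. The clock index was the mean centred log2 ratio of Per2, Per3, Dbp, Tef, Hlf and Ciart minus that of Arntl. It differed by -0.45 (permutation p 0.135, without slide), or by -0.54 with slide. Within slides 1 to 5 it differed by 0.25, -0.89, -0.40, -0.99 and -0.37. On days 1, 3 and 28 it differed by -0.18, -0.29 and -0.89. With the clock index as a covariate the glucocorticoid difference was -0.17 ± 0.071 (SE), and -0.16 ± 0.077 with slide added. That argues against the index as the whole cause, as far as an index with its own error can.

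Interferon response genes were higher in carbon black hearts, with a score difference of 0.12 for the mean of the 3 days. A single mouse does not account for the whole of this difference, since the lowest with 1 mouse left out was 0.086, without carbon black day 3 replicate 13. That mouse and control day 3 replicate 9, whose score stood out, were both on slide 2. There the score differed by 0.37, against -0.017 to 0.12 on the other slides. More immune cells stay open as a source, since the macrophage, T cell, B cell and neutrophil lists had medians from -0.030 to 0.053 against 0.11 for interferon, but the neutrophil score was above the control mean in 6 of 6 carbon black mice on day 28, as was the interferon score, the scores of the first 3 lists differed by 0.064 ± 0.087 (SE), -0.019 ± 0.063 and 0.045 ± 0.053, too wide a spread to tell, and with the Feature Extraction ratio the macrophage median was 0.12. As large a difference occurred in 10 of 100 splits, the real one included (highest other 0.16), and in 13 of 100 with slide, while 100000 permutations gave a p of 0.0766, so chance could not be excluded. An antiviral-type response to carbon black may be one explanation and remains untested.

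Slides 4 and 5 stood apart from slides 1 to 3 in their Cy5 detection. Across probes, the log2 ratios of slides 4 and 5 had a slope against those of slides 1 to 3 of 0.51 among probes with dimmer Cy5 and 0.83 among brighter probes. This is consistent with a lower Cy5 signal compressing the ratios, most among dim probes. Why the signal was lower was not tested, since slide and scan day coincide for these slides. Both treatments occurred on each slide, so no biological explanation was tested.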

How the results depend on the processing

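Tests without slides 4 and 5, with scaling between arrays, with an estimated correlation and slide together, and of lists without each array were chosen after the data were seen, and the others before the data were examined. The 7 counts of 0 called probes stayed at 0 in each setting run on all arrays or on slides 1 to 3, except for 32 with slide as a fixed term (control day 3 against day 1) and 1 with slide as a random block (mean of the 3 days, an unnamed probe at -0.23). Slide carried a correlation of 0.52, and removing it narrowed the median SE. Without 1 array the mean of the 3 days called 0 to 2 probes, the 2 being Klf2 (-0.79, adjusted p 0.0333) and an unnamed probe without control day 3 replicate 15, and the cause was not tested. By fry, 0 of the 136 pairs of list and comparison were called, with or without slide. Among the lists that camera called, the lowest fry adjusted p without slide was 0.996 on each single day. Of 25 list calls by camera, 1 remained with an estimated correlation and 0 with slide added. A slide term kept 14, the mean of all probes of a gene 22, and the arrays of slides 1 to 3 alone 8, with 14 lost. A further 3 turned there, namely fatty acid oxidation on day 1 (adjusted p 0.363), oxidative phosphorylation on day 3 (0.882) and calcium handling on day 3 (0.212), and the cause was not tested. There glucocorticoid targets kept their call for the mean (0.0175) and day 28 (0.00860) and lost it on day 1 (0.0641) and day 3 (0.742). Leaving out 1 array gave 16 to 34 calls, fewest without carbon black day 28 replicate 18, and kept 8 of the 25 calls throughout. Of 625 named gene values, those that took the other sign numbered 45 with the Feature Extraction ratio, 55 with Cy5 alone, 102 with median centring, 39 and 32 with slide fixed and random, 22 with scaling, 5 with the value table and 1 without background subtraction. Aquantile normalization left the ratios as they were and tested nothing. With only the arrays of 2 groups, the mean and the interaction cannot be had. Low Cy5 signal limits what slides 4 and 5 can show. On simulated data, 51.0% of 1.5-fold and 86.9% of 2-fold changes were recovered on 1 day, and 86.3% and 99.7% for the mean, with 4 and 2.8 false calls per draw. With slide they were 80.3% and 98.5% on 1 day and 96.1% and 99.7% for the mean, with 5.6 and 6 false calls per draw. Each draw mixed 1.5-, 2- and 3-fold changes over 200 probes, which eases the adjusted threshold. A 1.5-fold change among few others would be recovered less often. In the real mean of the 3 days without slide, 8 probes differed over 1.5-fold and 0 were called. The false calls were averaged over 5 draws, while another split of the mice without slide called 5651 probes for the mean. The changes were added at full size to log2 ratios already background corrected and normalized. These shares therefore leave out any compression of the ratios, and real changes in RNA, above all of dim probes, may be recovered less often.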

Other observations

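The tests of the probe counts by splits were chosen after the counts were seen, and those of the list calls and of the likeness between days were planned beforehand.

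Other splits of the mice show how far chance and slides can carry these results. A real count of 0 called probes is reached by any split, so the 100 of 100 found in each of the 7 comparisons tests nothing about chance. The highest counts among the others were 0 on day 1, 10428 on day 3, 315 on day 28, 5651 for the mean of the days, 1 for the interaction, 1 for control day 3 and 6391 for control day 28 against control day 1. Counts that high point to the slide structure, since with a slide term the highest counts were 1 on each single day and 20 for the mean. The 25 list calls were reached by 42 of 100 splits, the real one included (highest other 49), or by 33 of 100 with slide, so chance could not be excluded for their number.

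The hypothesis that carbon black changed the same genes on each day was tested by the correlation of the daily effects across genes, where genes are not independent replicates. Its mean over the 3 pairs of days was 0.075, and 31 of 100 splits gave as much (highest other 0.74). With slide it was 0.12, reached by 6 of 100 splits, so chance could not be excluded.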
